A study of Mus musculus with 16 samples.

How the data were processed

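RNA was taken from B16-F10 mouse melanoma cells after 24 hours with 1 of 4 antibodies, named in the labels Mel321-31, Mel322-34, Mel321-35 and MGO.53, the last an isotype control. Per the labels' protocols, polyadenylated RNA was enriched and strand-specific libraries were made. The labels describe 16 samples, 4 per antibody, and 15 were analysed here. Mel321-35 replicate 2 was not analysed here. Per the labels, Mel321-35 replicate 1 is the sole sample of batch 2 among the 15, and the other 14 belong to batch 1. Whether replicates came from separate cultures is not given beyond the word replicate, so p-values measure the spread between these samples.

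Per the submitters' processing notes, STAR 2.7.10a, HTSeq 2.01 and DESeq2 (version not given) were used. The genome build and annotation are not given in the sources used here, so no coordinates are printed. The authors deposited raw read counts per gene for 55414 Ensembl identifiers, of which 6250 held no value in any library and 49164 held values, 22365 of these 0 in all libraries. The authors also deposited a normalised signal per gene, which equalled the raw count divided by 1 size factor per library and was given for 19365 genes with a total of at least 10 counts. The tests used the raw counts, and the authors' size factors served as an alternative scaling. The table held 0 further columns of per-sample values and 0 lines that name no gene. Where several identifiers shared a symbol, it stayed with the identifier of most counts. Whether the strand was used in counting is not given in the sources used here, so levels of genes with an antisense partner are uncertain, and reads of near-identical genes cannot be divided from counts alone.

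Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter by group and the quasi-likelihood F-test, in 1 fit over the 4 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14633 genes tested. The fit used the 14 batch 1 libraries, with n = 4 for Mel321-31, Mel322-34 and MGO.53 and n = 2 for Mel321-35. The design fixed before the data were examined had counted on 15 batch 1 libraries, 3 of them of Mel321-35. The biological coefficient of variation was 5.46% with 10 residual degrees of freedom. The standard error of a log2 fold change was its absolute value divided by the square root of F. Levels are in CPM, counts scaled to a library total of 1000000, with TMM scaling. Summed CPM, levels of the keratin and mesothelin set and shares of the batch 1 mean used the total count alone. Library totals, mitochondrial shares of the counts and summed CPM were compared between groups by exact two-sided permutation tests, on log2 values for summed CPM.

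Before the data were examined, 30 gene lists were fixed, covering heat shock and other stress responses, cell cycle, cell death, inflammation, pigmentation and invasion, metabolism, RNA quality and markers of other cell types. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1, on voom weights, with a preset correlation of 0.01 and adjustment over the lists of a comparison. That left 27 lists, and 3 were not tested. Each list test was repeated with an estimated correlation, and with fry, which asks whether the members move one way on balance.

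The genes named were chosen by a rule fixed before the data were examined. For each antibody against MGO.53 it took the 8 largest changes in each direction among called genes whose libraries did not overlap between the groups, with an average log2 CPM of at least 1 and an official symbol. It added the 3 members with the smallest p of each list that passed, in the list's direction, and always Hspa1a, Hspa1b, Hspa8, Hsp90aa1, Hsph1 and Dnajb1. Between antibodies it took the 4 largest changes in each direction, or all where fewer passed. A gene that entered through a list or as a partner of HSP70 kept its place whatever its level. Not every gene that the rule took is named in the text.

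Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, 3 other scalings, other filters on low counts, a stricter threshold, a test against a 1.5-fold change, fits of 2 groups alone, all 15 libraries with and without a batch term, the replicate number as a block, and each library left out in turn. Added after the data were seen were a fit without 95 transcripts that were at least 8-fold lower in the batch 2 library than in the batch 1 mean (batch 1 mean at least 1 CPM), a fit with the log2 summed CPM of those transcripts as a covariate, and a fit with the trend on transcript length removed from each library. A set of 20 epithelial markers was written after the 95 transcripts had been seen, and the 11 of them among the 95 are called the keratin and mesothelin set. Transcript length and GC content came from the longest GENCODE M21 transcript of each Ensembl identifier. Calls shared by antibodies were set beside 10 simulated sets of unchanged groups and beside fits with the 4 controls split 2 and 2.

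Replicate pairs of 1 group differed by 2.89 to 11.3 times the counting noise (chi-square per degree of freedom, 21 pairs), so no library appeared again within its group. The pipeline was tested on simulated data with known changes. For Mel321-31 against MGO.53, with 14279 simulated genes tested, it called 56.7% of genes changed 1.25-fold, 67.2% of those changed 1.5-fold and 78.8% of those changed 2-fold. For Mel322-34 with 14294 genes tested the shares were 55.2%, 56.7% and 83.3%, and for Mel321-35 with 14294 they were 41.8%, 70.1% and 71.2%. Of the genes called in the simulations, 5.92%, 4.86% and 6.57% were unchanged ones for these 3 comparisons, and 6.90% for Mel321-31 against Mel322-34, 9.35% for Mel321-31 against Mel321-35 and 3.12% for Mel322-34 against Mel321-35, with 1 simulation each. Figures were drawn with matplotlib 3.10.9.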

Results

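The series set out to learn which genes and pathways go up or down when B16-F10 cells, a pigmented mouse melanoma line, meet antibodies that its title calls decoys for extracellular HSP70. Messenger RNA was sequenced after 24 hours with the antibody Mel321-31 (n = 4), Mel322-34 (n = 4) or Mel321-35 (n = 3, of which 1 in batch 2) or with the isotype control MGO.53 (n = 4). Total counts ran from 19446531 in MGO.53 replicate 2 to 37957845 in Mel321-31 replicate 3. The mean was 35.9 ± 2.88 M counts (SD, n = 4, where M stands for 1000000) for Mel321-31, 32.0 ± 2.42 M (n = 4) for Mel322-34 and 26.2 ± 5.76 M (n = 4) for MGO.53. The Mel321-35 libraries held 26.1 (batch 2), 35.2 and 26.2 M counts. The difference in total between Mel321-31 and MGO.53 gave p = 0.0571 in an exact two-sided permutation test, where 0.0286 is the smallest possible, and 0.257 after adjustment over 9 such tests. The mitochondrial share of the counts, also a sign of RNA quality, was 1.96 ± 0.0868% with Mel321-31, 2.05 ± 0.107% with Mel322-34 and 2.21 ± 0.215% with MGO.53 (SD, n = 4 each, 2.47% in MGO.53 replicate 2) and 2.00% and 2.16% in the batch 1 libraries of Mel321-35, with exact p = 0.0857, 0.200 and 0.467 against MGO.53 and 0.257 for Mel321-31 after the same adjustment, with larger values for the other 2.

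The single batch 2 library, Mel321-35 replicate 1, held 95 transcripts that were at least 8-fold lower there than in the batch 1 mean, and 0 that were as much higher. Among these batch-1-only transcripts were the epithelial keratins Krt8 and Krt18, the interferon-induced Oasl1 and the prostaglandin synthase Ptgs2. Their summed level was 11.7 CPM in the batch 2 library, 209 ± 38.6 CPM (SD, n = 4) in Mel321-31, 341 ± 157 CPM (n = 4) in Mel322-34 and 498 ± 137 CPM (n = 4) in MGO.53. The batch 1 libraries of Mel321-35 had 282 CPM in replicate 3 and 448 CPM in replicate 4. Mel321-31 held 0.419 times the MGO.53 level, with every Mel321-31 library below every MGO.53 library (exact two-sided permutation p = 0.0286, the smallest possible, and 0.257 adjusted over the 9 tests). For Mel322-34 and Mel321-35 the exact p was 0.143 and 0.333. The comparisons that follow used batch 1 libraries, so Mel321-35 had n = 2.

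The HSP70 genes themselves did not pass the test with any antibody. Hspa8 (ENSMUSG00000015656), the constitutive cytosolic HSP70, stood at 2032 ± 46.4 CPM with Mel321-31 and 2019 ± 53.5 CPM with MGO.53 (SD, n = 4 each), a log2 fold change of 0.0090 ± 0.026 (SE). With Mel322-34 its log2 fold change was -0.055 ± 0.026 (adjusted p = 0.208) and with Mel321-35 it was -0.10 ± 0.032 (adjusted p = 0.234, edgeR). The inducible Hspa1b had 2.90, 3.34 and 4.16 CPM with Mel321-31, Mel322-34 and Mel321-35 against 2.98 CPM with MGO.53, with log2 fold changes of -0.036 ± 0.18, 0.18 ± 0.18 and 0.49 ± 0.22. Hspa1a, its near-identical copy, had too few counts to be tested, and how reads of the pair were divided is uncertain. The chaperones Hsp90aa1 (0.051, -0.032 and 0.039), Hsph1 (0.016, 0.043 and 0.0032) and Dnajb1 (0.036, 0.0092 and -0.042) did not pass in any of the 3 comparisons. Of 21 heat shock genes, 0 rose and 0 fell with Mel321-31 (edgeR, 4 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom), the regulator Hsf1 (-0.16) and the co-chaperone Bag3 (-0.15) fell with Mel322-34, and Dnajb4 rose with Mel321-35. Adjusted over the list alone, the counts higher and lower were 0 and 0, 0 and 2, and 1 and 2. The list did not pass for any of the 3, with adjusted p = 0.680, 0.109 and 0.875 (camera). Hsf1 and Bag3 were chosen after their values were seen.

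With Mel321-31, the keratins Krt8 and Krt18 and 19 of 31 interferon-stimulated genes fell, and the call of the interferon list was lost with adjusted p = 0.174 with an estimated correlation. Relative to MGO.53, 517 of 14633 genes changed, 206 higher and 311 lower (edgeR, adjusted p under 0.05). Krt8 (ENSMUSG00000049382) had 2.15 ± 0.388 CPM against 6.12 ± 1.14 CPM (SD, n = 4 each), a log2 fold change of -1.50 ± 0.23 (SE, adjusted p = 0.000778), and Krt18 had -1.43 ± 0.27. Among genes of at least 1 average log2 CPM whose libraries did not overlap between the groups, the largest decreases also took in the phosphatase gene Ppef1 (-1.66 ± 0.25), the MAP kinase phosphatase Dusp5 (-1.61), Slfn4 (-1.50), Apol9a (-1.46), Ifi203 (-1.44) and the AP-1 subunit Fosl1 (-1.44). These 8 genes had 0 to 0.350 CPM in the batch 2 library. Of the lower genes, 118 fell by 2-fold or more, of which 72 were among the 95 batch-1-only transcripts and 116 had a batch 2 level below 0.5 times the batch 1 mean. By the same choice the largest increases were those of Myef2l (0.61 ± 0.13), Btbd8 (0.39), Klhl11 (0.38), Rpgrip1l (0.37), Slfn3 (0.35), Zfp81 (0.35), the amino acid transporter Slc6a15 (0.35) and Dixdc1 (0.34). Of the higher genes 1 rose by 2-fold or more, Gm4755 (2.28), chosen after its values were seen.

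Of 31 interferon-stimulated genes, 19 fell and 12 did not pass with Mel321-31, and 27 fell when adjusted over the list alone (median log2 fold change -0.72, camera adjusted p = 9e-24). Isg15 (ENSMUSG00000035692), a ubiquitin-like modifier, had 10.7 ± 1.36 CPM against 22.5 ± 5.94 CPM (log2 fold change -1.07 ± 0.16), its protease Usp18 had -1.18 ± 0.18 and Oasl1 had -1.32 ± 0.21. Members with a batch 2 level below 0.5 times the batch 1 mean had a median of -0.95 (17 of 20 fell), and the other members had a median of -0.21 (2 of 11 fell). Among 20 genes of MHC class I antigen presentation 9 fell, or 13 adjusted over the list alone, among them the peptide transporter Tap1 (-0.86), the heavy chain H2-D1 (-0.39 ± 0.079) and the immunoproteasome subunit Psmb8 (-1.40). Among 24 NF-kB targets 6 fell, or 12 adjusted over the list alone, including Ptgs2 (-1.31), the chemokine Cxcl10 (-0.93) and the feedback inhibitor Tnfaip3 (-1.11). These list calls were lost with an estimated correlation, with adjusted p = 0.174 with an estimated correlation for interferon, 0.174 for antigen presentation and 0.223 for NF-kB. The batch-1-only transcripts included 9, 2 and 5 members of these lists, and all 95 had a median log2 fold change of -1.28.

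With Mel321-31, 7 other lists passed, and all 7 calls were lost with adjusted p from 0.174 to 0.771 with an estimated correlation. With fry, 1 list passed in this comparison, the integrated stress response (adjusted p = 0.0287). Of 23 integrated stress response genes 3 fell, the transcription factor Cebpb (-0.66), Trib3 (-0.58) and Nupr1 (-0.98), or 6 adjusted over the list alone (list adjusted p = 0.174 with an estimated correlation). Of 28 immediate early genes 4 fell, Dusp5, Fosl1, Egr1 (-0.98) and the proto-oncogene Myc (-0.24 ± 0.043), and 6 were lower and 1 higher adjusted over the list alone, with 1 member among the batch-1-only transcripts (adjusted p = 0.174 with an estimated correlation). Of 43 cytosolic ribosomal proteins 8 fell, among them Rpl28 (-0.23) and Rps27 (-0.24), or 14 adjusted over the list alone (adjusted p = 0.425 with an estimated correlation). The median over that list was -0.080, or -0.037 with 6 called once the trend on transcript length was removed, and against the MGO.53 mean it was 0.0827 in replicate 1 and -0.137 to -0.115 in the other 3 libraries. The respiratory chain genes Uqcrq (-0.24) and Cyc1 (-0.11) fell among 34 (2 adjusted over the list alone, adjusted p = 0.771 with an estimated correlation for the list), and mt-Nd4 (-0.34), mt-Cytb (-0.21) and mt-Nd2 (-0.25) fell among 7 mitochondrially encoded genes, a list that is also a sign of RNA quality (5 adjusted over the list alone, adjusted p = 0.174 with an estimated correlation for the list). The antioxidant NRF2 list passed as lower with 0 of 26 members called (edgeR, 7 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone), with Nfe2l2 at -0.11, Gsr at -0.11 and Osgin1 at -0.16 (adjusted p = 0.174 with an estimated correlation). The hypoxia list passed as higher with 0 of 23 called (edgeR, 9 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom) and 5 higher adjusted over the list alone, with Kdm3a at 0.13, Plod2 at 0.15 and P4ha1 at 0.13 (adjusted p = 0.310 with an estimated correlation).

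For Mel321-31 the other 17 lists did not pass, with adjusted p from 0.0644 to 0.867 (camera). The 517 genes became 1238 (665 higher, 573 lower) without Mel321-31 replicate 1, 136 without its replicate 2, 253 without its replicate 3, 218 without its replicate 4, 163 without MGO.53 replicate 2 and 187 without MGO.53 replicate 4. They became 5 (4 higher, 1 lower) with the summed amount of the 95 transcripts as a covariate, an amount that separates the 2 groups, 91 (54 higher, 37 lower) with the batch 2 library included and no batch term, 517 (207 higher, 310 lower) with that library and a batch term, which absorbs that 1 library, and 0 against a 1.5-fold threshold (309 at an unadjusted p under 0.05, edgeR), while DESeq2 and limma-voom without that threshold called 737 and 459.

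With Mel322-34 more genes passed, with small changes. Against MGO.53, 1005 genes changed, 589 higher and 416 lower (edgeR, adjusted p under 0.05), with a median absolute log2 fold change of 0.19 among them. Scube3 (ENSMUSG00000038677), which encodes a secreted glycoprotein, rose from 23.7 ± 1.07 to 34.4 ± 1.38 CPM (SD, n = 4 each), a log2 fold change of 0.54 ± 0.057 (SE, adjusted p = 2.58e-06). Chosen in the same way as for Mel321-31, further increases included those of the sulfotransferase Chst11 (0.76), Spsb1 (0.54), Neb (0.52), Ypel2 (0.47), Klhl11 (0.47) and Myef2l (0.46). The decreases so chosen were those of Krt8 (-0.84 ± 0.22), Exoc3l4 (-0.79), Plekha4 (-0.70), Ier5l (-0.46), S100a6 (-0.45), Fmc1 (-0.43), the biliverdin reductase Blvrb (-0.41) and the urokinase receptor Plaur (-0.40). With upper quartile scaling the split was 483 higher and 555 lower, in place of 589 and 416.

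Ribosomal protein, NRF2 target and mitochondrial lists passed as lower with Mel322-34. Of 43 cytosolic ribosomal proteins 25 fell, or 36 adjusted over the list alone (median -0.15, camera adjusted p = 1.18e-24), for example Rpl37 (-0.25) and Rpl19 (-0.22 ± 0.040). This call was lost with adjusted p = 0.215 with an estimated correlation. Across genes with an average log2 CPM above 2 the log2 fold change rose with transcript length (Spearman 0.512, genes not being independent replicates). With that trend removed 7 of the 43 fell and the median was -0.056. Of 26 NRF2 targets 10 fell, or 13 adjusted over the list alone, among them the iron storage chains Fth1 (-0.20 ± 0.038) and Ftl1 (-0.16 ± 0.034) and the sulfiredoxin Srxn1 (-0.16). The NRF2 list also passed with adjusted p = 0.0312 with an estimated correlation. How far the length trend carries this list or the other lists of Mel322-34, here or against another antibody, is not given. The calls over all genes fell with that trend removed, as stated below. Of 34 respiratory chain genes 5 fell, or 12 adjusted over the list alone, with Uqcrq at -0.26, Atp5o at -0.21 and Uqcrc1 at -0.14 (adjusted p = 0.274 with an estimated correlation). Ribosome biogenesis had 2 of 30 lower, Srm (-0.22) and Nop2 (-0.11), or 3 adjusted over the list alone, with Rrp12 at -0.15 not passing (adjusted p = 0.253 with an estimated correlation). The mitochondrially encoded mt-Nd4 fell (-0.21), 1 of 7, or 4 adjusted over the list alone (adjusted p = 0.451 with an estimated correlation). With fry, which does not compare a list with other genes, ribosomal proteins, NRF2 targets and ribosome biogenesis passed (adjusted p = 0.0374, 0.00113 and 0.0374). The respiratory chain and mitochondrially encoded lists did not pass with fry (adjusted p = 0.0621 and 0.381).

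Cell cycle lists passed in both directions with Mel322-34. In the G2 and mitosis list 6 of 28 genes rose, or 10 adjusted over the list alone, among them the kinetochore gene Cenpf (0.23), the proliferation marker Mki67 (0.21) and the topoisomerase Top2a (0.15). In the DNA replication list the licensing factor Cdt1 (-0.24) and Chaf1b (-0.17) fell and the polymerase Pola1, chosen after its values were seen, rose (0.17) among 30, or 5 lower and 1 higher adjusted over the list alone, with Rrm2 at -0.092 not passing. The list calls were lost, with adjusted p = 0.215 with an estimated correlation for mitosis and 0.0803 for replication, while both passed with fry (adjusted p = 0.0159 and 0.00121). Of 28 immediate early genes Myc (-0.26 ± 0.043), Nr4a1 (-0.21) and Nr4a3 (-0.14) fell and Spred1, chosen after its values were seen, rose (0.18), or 7 lower and 1 higher adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). In the hypoxia list the collagen-modifying Plod2 (0.23) and P4ha1 (0.19) and the kinase Pdk1 (0.31) rose among 23, or 5 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). In the integrated stress response list Slc3a2 (-0.17) and Shmt2 (-0.14) fell among 23, or 3 adjusted over the list alone, with Trib3 at -0.37 not passing (adjusted p = 0.223 with an estimated correlation). The immediate early, hypoxia and integrated stress response lists passed with fry (adjusted p = 0.0374, 0.0312 and 0.0450).

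The inflammatory lists also passed as lower with Mel322-34, with few members called. Usp18 fell (-0.61 ± 0.17) among 31 interferon-stimulated genes, or 9 adjusted over the list alone, with Irf7 at -0.69 and Oasl2 at -0.61 not passing. B2m (-0.19) and H2-D1 (-0.28) fell among 20 antigen presentation genes, 2 adjusted over the list alone, with Tap1 at -0.41 not passing. Of 24 NF-kB targets 0 were called (edgeR, 3 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom, 0 adjusted over the list alone), with Rela at -0.14, Tnfaip3 at -0.58 and Cxcl10 at -0.43. The list calls were lost, with adjusted p = 0.463 with an estimated correlation for interferon, 0.388 for antigen presentation and 0.511 for NF-kB. The 95 batch-1-only transcripts had a median log2 fold change of -0.56 in this comparison, and 7 of them passed, all lower. The other 14 lists did not pass (camera adjusted p from 0.0530 to 0.946). The 1005 genes became 327 without Mel322-34 replicate 3, 397 without MGO.53 replicate 2, 504 without MGO.53 replicate 4, 371 with the batch-1-only amount as a covariate and 411 (175 higher, 236 lower) with the length trend removed. Against a 1.5-fold threshold the count was 0 (105 at an unadjusted p under 0.05, edgeR), while DESeq2 and limma-voom without that threshold called 1397 and 908.

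**Figure D1:**
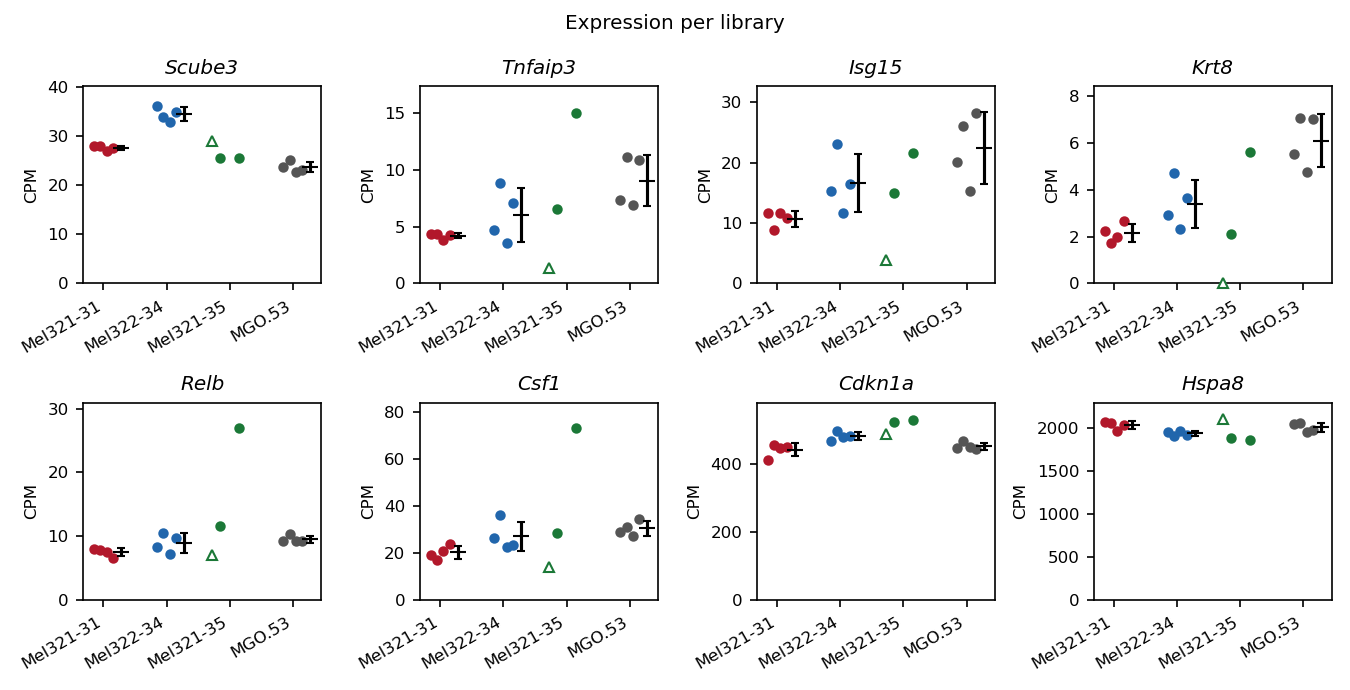
Level of 8 genes in each library, in CPM on linear axes from 0. Filled circles are batch 1 libraries, the open triangle is the batch 2 library, and bars give mean ± SD for groups of n = 4. Scube3 lay above every MGO.53 library in all 4 Mel322-34 libraries, and Relb and Csf1 were highest in Mel321-35 replicate 4.

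With Mel321-35, 6 genes passed against MGO.53 (edgeR, n = 2 against 4), 5 higher and 1 lower. The cell cycle inhibitor Cdkn1a (ENSMUSG00000023067) rose from 453 ± 11.1 to 526 ± 6.06 CPM (log2 fold change 0.21 ± 0.040, adjusted p = 0.0353), the glycolytic enzyme Pfkl rose by 0.26 ± 0.048, the HSP70 partner Dnajb4 by 0.39 ± 0.072 and the NF-kB subunit Relb by 1.00 ± 0.19, while the kinase Mknk2 changed by -0.20 ± 0.040. Junb, an AP-1 subunit chosen after its values were seen, rose by 1.00 ± 0.18. Relb stood at 11.6 CPM in replicate 3, 27.0 CPM in replicate 4 and 7.12 CPM in the batch 2 library, Junb at 41.7, 107 and 37.3 CPM, and the cytokine Csf1, chosen after its values were seen and not passing, at 28.7, 73.1 and 14.1 CPM. The NF-kB list passed as higher with Relb called, Nfkb2 at 0.52 and Cxcl1 at 2.19, and with 0 members called by DESeq2 and 0 by limma-voom (10 at an unadjusted p under 0.05, edgeR), and 9 members higher and 1 lower adjusted over the list alone (adjusted p = 0.724 with an estimated correlation). Against the MGO.53 mean the list median was -0.118 in replicate 3 and 0.565 in replicate 4 (log2), so the direction turned between the 2 libraries. Of its 24 members 5, Cxcl1 among them, were batch-1-only transcripts. The p53 target list passed as higher (median 0.11) with Cdkn1a called, Mdm2 at 0.24 and Trp53inp1 at 0.30, and with 6 of 19 members higher adjusted over the list alone (adjusted p = 0.252 with an estimated correlation).

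A further 11 lists passed for Mel321-35 with 0 members called by edgeR, while 2 to 11 members per list had an unadjusted p under 0.05, 0 to 2 passed with DESeq2 and 0 with limma-voom. Higher were G2 and mitosis (Kif23 0.16, Top2a 0.12, Hmmr 0.14) and hypoxia (Fam162a 0.22, P4ha1 0.20, Plod2 0.20), the former with 0 and the latter with 8 members higher and 1 lower adjusted over the list alone. Lower were DNA replication (Cdt1 -0.17, Pole -0.16, Tyms -0.15), interferon-stimulated genes (Ifi44 -0.66, Irf7 -0.60, Oas3 -0.63), antigen presentation (Psmb8 -0.85, Psme2 -0.19, Tap2 -0.54), ribosome biogenesis (Srm -0.15, Nop56 -0.095, Rrp12 -0.14), ribosomal proteins (Rps27 -0.20, Rpl19 -0.15, median -0.070, or -0.035 with the length trend removed) and mitochondrially encoded genes (mt-Nd4 -0.17, mt-Cytb -0.15, mt-Co1 -0.11), each with 0 members called adjusted over the list alone. Also lower were melanocyte differentiation (Trpm1 -0.15, Pmel -0.12, Sox10 -0.090) and fatty acid synthesis (Fasn -0.18, Elovl1 -0.15, Srebf1 -0.098), each with 2 members lower adjusted over the list alone, and the respiratory chain (Uqcrq -0.22, Uqcrc1 -0.10, Atp5o -0.15), with 1. None of the 13 passing lists held with an estimated correlation (adjusted p from 0.179 to 0.724), and 1 passed with fry, DNA replication (adjusted p = 0.0347). The batch-1-only transcripts had a median log2 fold change of -0.48. The 6 genes became 0 without Mel321-35 replicate 4 or without any 1 of the 4 MGO.53 libraries (edgeR, 1203 to 1555 at an unadjusted p under 0.05), 21 without replicate 3, 42 (18 higher, 24 lower) in a fit of these 2 groups alone and 52 with the covariate. DESeq2 called 123 (52 higher, 71 lower), of which 3 were among the 6, and limma-voom 4.

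**Figure D2:**
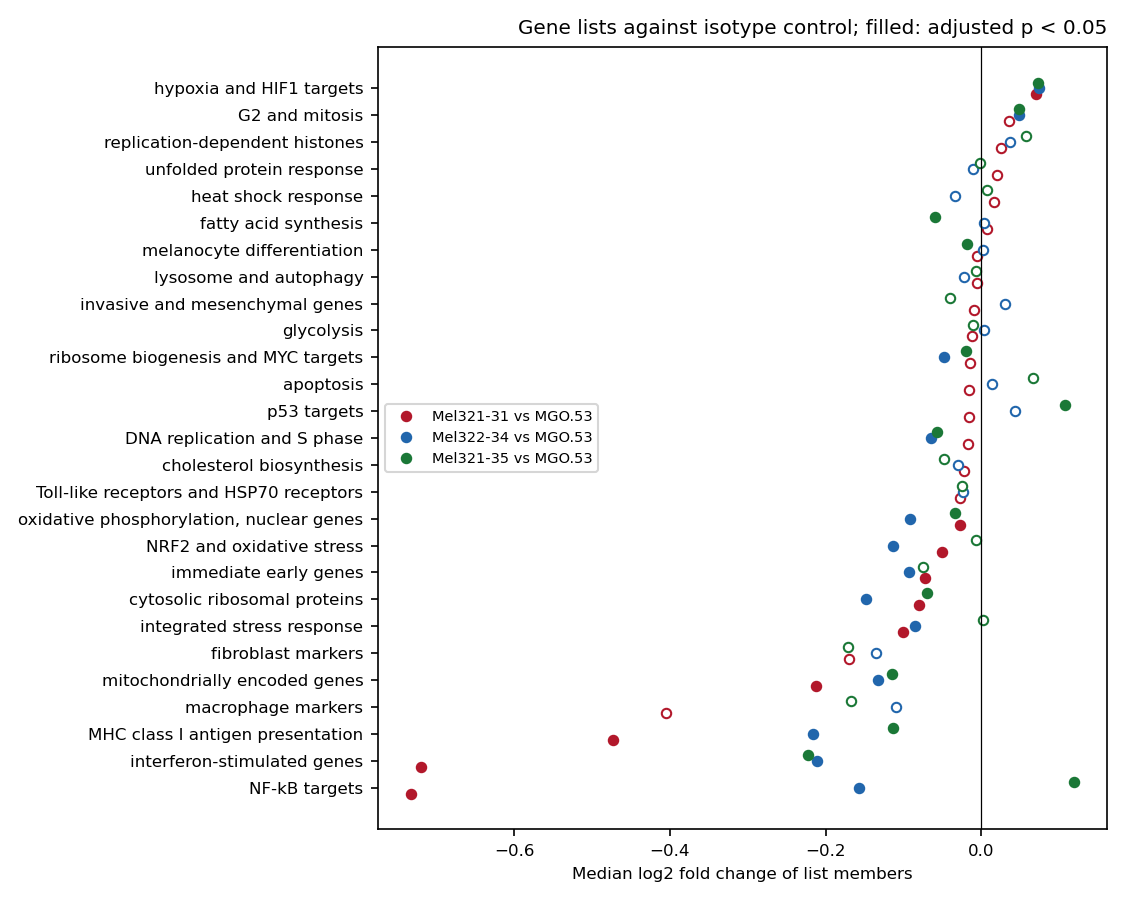
Median log2 fold change of the members of each of 27 gene lists (horizontal axis) for the 3 antibodies against MGO.53. Filled circles passed camera with the preset correlation, open circles did not. The NF-kB list lies at -0.73 for Mel321-31 and 0.12 for Mel321-35.

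Compared directly, Mel321-31 and Mel322-34 differed in 3 genes, all lower with Mel321-31 (edgeR). These were Scube3 (-0.32 ± 0.055, adjusted p = 0.0168), Pmepa1 (-0.29 ± 0.048), an inhibitor of TGF-beta signalling, and the receptor Erbb3 (-0.25 ± 0.044). Of the lists 13 passed for this pair and 3 of them held, DNA replication (median 0.045) and NRF2 targets (0.062) higher and invasive genes (-0.041) lower with Mel321-31, each with adjusted p = 0.0233 with an estimated correlation. In these 3 lists 0 members were called (edgeR), 3, 8 and 4 had an unadjusted p under 0.05, 0, 0 and 2 passed with DESeq2, and 0, 0 and 1 with limma-voom. Adjusted over the list alone the called members were 0, 2 higher and 2 lower. The interferon list was lower with Mel321-31 (median -0.44, 21 lower adjusted over the list alone, adjusted p = 0.124 with an estimated correlation), and the batch-1-only transcripts had a median of -0.71. The 3 genes became 0 in the fits without Mel321-31 replicate 2, 3 or 4 or Mel322-34 replicate 1 or 4 (edgeR, 1001 to 1111 at an unadjusted p under 0.05), and 9 passed with DESeq2 and 4 with limma-voom on all libraries.

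Relative to Mel321-35, 15 genes passed with Mel321-31 and 38 with Mel322-34 (edgeR). With Mel321-31, Enpp2 (0.34 ± 0.056), which makes lysophosphatidic acid, and Abca12 (0.29) were higher and 13 genes were lower, among them Relb (-1.35 ± 0.18), Tnfaip3 (-1.35), Csf1 (-1.32) and Junb (-1.17). Of 24 NF-kB targets 9 were lower with Mel321-31, or 15 adjusted over the list alone (adjusted p = 0.105 with an estimated correlation), and the batch-1-only transcripts had a median of -0.81. With Mel322-34, 28 genes were higher, among them Hipk2 (0.51), Xylt1 (0.51), Kmt2c (0.44) and Zfp41 (0.44), and 10 were lower, among them Relb (-1.10), Junb (-1.04), Zc3h12a (-0.82) and Nfkb2 (-0.54). The NF-kB list had 5 members lower, or 10 adjusted over the list alone (adjusted p = 0.477 with an estimated correlation). The NRF2 list was lower (median -0.090) with Srxn1 called, or 8 adjusted over the list alone, and held with adjusted p = 0.0146 with an estimated correlation. Without Mel321-35 replicate 4 both counts became 0 (edgeR, 589 and 730 at an unadjusted p under 0.05), as did the 15 with the batch-1-only amount as a covariate (edgeR, 741 at an unadjusted p under 0.05), where the 38 became 78, while DESeq2 called 24 and 139 and limma-voom 3 and 22 on all libraries. The 15 genes became 45 (26 higher, 19 lower), 6, 7 and 9 without Mel321-31 replicates 1, 2, 3 and 4 in turn and 43 without Mel321-35 replicate 3, and the 38 became 15, 12 and 58 without Mel322-34 replicates 1, 3 and 4 in turn, 45 (18 higher, 27 lower) without Mel321-35 replicate 3 and 23 (9 higher, 14 lower) with the length trend removed.

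Mel321-31 and Mel322-34 had 265 called genes in common against MGO.53, 163 higher and 102 lower in both, with 0 in opposite directions. Independent lists of those sizes would share 8.29 higher and 8.84 lower genes. The log2 fold changes correlated across 9282 genes with r = 0.780 (genes not being independent replicates), against 0.517 in 10 simulated sets of unchanged groups against the same controls, and their covariance was 0.00931 against 0.00220. With the 4 controls split 2 and 2, the shared genes numbered 0 to 26 over 6 fits with a median of 12, with fewer controls behind each call. The median correlation was then 0.523 and the median covariance 0.00720. The 2 comparisons of such a fit share no control library, so the simulated 0.517 and 0.00220 are not their reference. The covariance with all controls, less the simulated one, was 0.00712. Mel321-35 shared 2 called genes with each of the others, Pfkl higher and Mknk2 lower in both cases. Its covariance was 0.00594 with Mel321-31 and 0.00639 with Mel322-34, against simulated values of 0.00220 and 0.00217. The simulated sets drew each gene on its own, without differences between libraries that many genes share, such as the trend on transcript length. Neither they nor the split controls can tell a response common to the antibodies from a difference of the MGO.53 libraries as a group.

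**Figure D3:**
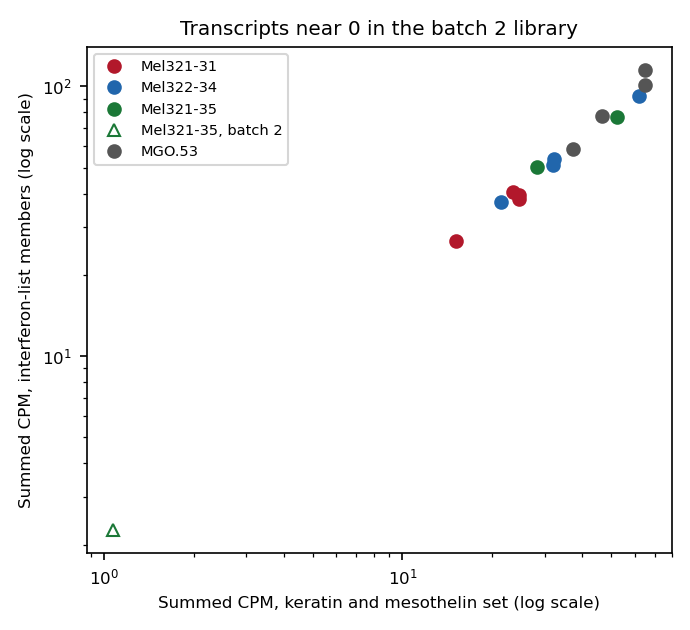
Summed CPM of 9 interferon-list members against summed CPM of 11 keratin and mesothelin-set transcripts, both among the 95 batch-1-only transcripts, on log axes. Each point is a library, and the open triangle is the batch 2 library. The 4 Mel321-31 libraries lie between 15.1 and 24.6 CPM on the horizontal axis and the 4 MGO.53 libraries between 37.4 and 65.2 CPM.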

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

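Chosen only after the result was seen were the tests of the ratio of marker sets, of a mixture, of depth, of transcript length and both tests of the NF-kB pattern, along with the covariate and length trend fits, while the test of GC content was set before. In groups of 4 libraries, a value is given below where 1 library lay far from the other 3 for its range, leaving out genes with under 3 counts in every library of the group. Chance gives this in about 1 of 20 groups, or 23.4 of the 468 examined, and it was seen in 36, of which 17 were in Mel321-31 replicate 1.

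The batch 2 library, left out of the reported comparisons, held 95 transcripts at least 8-fold below the batch 1 mean, against 1 in MGO.53 replicate 2 and 0 in the other batch 1 libraries. Of the 118 decreases of 2-fold or more with Mel321-31, 72 were in these transcripts, and lower depth of the controls is argued against, since counts of the 95 before any scaling were lower with Mel321-31, by a summed log2 difference of -0.758 ± 0.254 (SE), although its totals were larger. A candidate explanation is RNA of other cells, or of another state of the line, present in batch 1 in differing amounts: the log2 ratio of interferon-list to keratin and mesothelin-set transcripts differed between Mel321-31 and MGO.53 by 0.0251 ± 0.0612 while the latter set differed by -1.28. A weaker interferon response of the melanoma cells cannot be told apart from it, because the mixture prediction takes the cells' own level from 1 library. The median residual after the change so predicted was -0.000392 ± 0.0390 (SE over the 31 genes, which leaves out the spread between libraries). The source is open, since the 20 epithelial markers were listed after the 95 transcripts had been seen and include 11 of them, 1 (Sfn) is also in the keratinocyte list, 1 reached 1 CPM in batch 2, Anxa3, the most abundant, had 5.70 to 12.5 CPM in the 4 MGO.53 libraries, and an effect of Mel321-31 on such cells was not tested.

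The ribosomal protein list passed as lower with Mel322-34 with a median log2 fold change of -0.15 and 25 of 43 members called. This list call was lost with adjusted p = 0.215 with an estimated correlation and passed with fry (adjusted p = 0.0374). In these libraries GC content is argued against as the source of this list's decrease, since the median against GC-matched genes was -0.134 ± 0.0117 (SE over the 43 genes). Across genes with an average log2 CPM above 2 the log2 fold change did fall with GC content (Spearman -0.449, genes not being independent replicates). A difference between libraries that follows transcript length may carry part of the list's decrease, since the median against length-matched genes was -0.0692 ± 0.0159 (SE over the 43 genes). With the length trend removed the median went from -0.15 ± 0.014 to -0.056 ± 0.015 (bootstrap SE), with 7 members called in place of 25 because the change shrank. How much belongs to length and how much to the antibody cannot be told apart. The remainder lies within 2 SE of the bound of -0.05 set for the test. These SE come from resampling genes that move together (estimated correlation 0.635) and leave out the spread between libraries. Neither matched test therefore weighs the decrease against that spread.

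The NF-kB list passed as higher with Mel321-35, with 1 of 24 members called by edgeR (10 at an unadjusted p under 0.05) and 0 by DESeq2 and by limma-voom, and the call was lost with adjusted p = 0.724 with an estimated correlation. The list median was 0.565 in replicate 4 (log2, against the MGO.53 mean) and -0.118 in replicate 3. RNA of other cells as in the pattern above may contribute and cannot be told apart with 1 library, although the keratin and mesothelin set in replicate 4 lay below the highest MGO.53 library by a log2 ratio of -0.320 ± 0.0524 (counting SE). A response of that 1 sample to the antibody or to its handling was not tested and stays open.

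Mel321-31 replicate 1 was the highest of its group for Fth1 (2391 CPM), Ftl1 (4081 CPM), H2-D1 (101 CPM), Hsp90aa1 (1510.4 CPM), Nupr1 (4.74 CPM), Pmel (6613 CPM), Rpl19 (932 CPM), Rpl37 (370.1 CPM), Slc3a2 (441 CPM), Tyms (91.6 CPM), Uqcrq (216 CPM) and the list median of cytosolic ribosomal proteins (0.0827). Mel321-31 replicate 1 was the lowest of its group for Cdkn1a (412 CPM), Hsph1 (161 CPM), Mdm2 (159.7 CPM), Slfn3 (13.6 CPM) and Trp53inp1 (66.7 CPM). Mel321-31 replicate 2 was the highest of its group for the list median of fibroblast markers (0.0129). Mel321-31 replicate 2 was the lowest of its group for Krt18 (1.05 CPM) and Oasl2 (3.04 CPM). Mel321-31 replicate 3 was the highest of its group for the list median of replication-dependent histones (0.797). Mel321-31 replicate 3 was the lowest of its group for Cenpf (127 CPM), Fasn (846 CPM) and Tnfaip3 (3.84 CPM). Mel322-34 replicate 1 was the highest of its group for Cyc1 (287 CPM), Ftl1 (3759 CPM) and Sox10 (602 CPM). Mel322-34 replicate 2 was the highest of its group for Oas3 (7.51 CPM). Mel322-34 replicate 4 was the highest of its group for Chaf1b (78.4 CPM). MGO.53 replicate 1 was the lowest of its group for Dnajb4 (22.2 CPM) and Pmepa1 (38.5 CPM). MGO.53 replicate 2 was the highest of its group for Relb (10.4 CPM). MGO.53 replicate 2 was the lowest of its group for Srm (121 CPM). MGO.53 replicate 3 was the highest of its group for Spsb1 (17.8 CPM). MGO.53 replicate 3 was the lowest of its group for Rpl19 (908 CPM). MGO.53 replicate 4 was the highest of its group for P4ha1 (96.3 CPM).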

How the results depend on the processing

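Chosen only after the data were seen were the fits with the covariate, with the length trend removed and without the 95 transcripts. Counts of genes are in the order Mel321-31, Mel322-34 and Mel321-35 against MGO.53, Mel321-31 against Mel322-34, Mel321-31 against Mel321-35 and Mel322-34 against Mel321-35, and counts of lists in the same order. The values in the report were 517, 1005, 6, 3, 15 and 38 genes and 10, 13, 13, 13, 11 and 5 lists. Leaving out each library in turn gave 136 to 1238, 327 to 1051, 0 to 21, 0 to 2, 0 to 45 and 0 to 58 genes (edgeR, 589 to 1555 at an unadjusted p under 0.05 where the count was 0) and 8 to 11, 11 to 14, 6 to 11, 13 to 15, 8 to 12 and 4 to 12 lists, where a lone Mel321-35 library was assumed to vary like the other groups. The cause was not tested for any change below except where named.

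The genes were 737, 1397, 123, 9, 24 and 139 with DESeq2, 459, 908, 4, 4, 3 and 22 with limma-voom, 763, 1202, 95, 110, 144 and 155 with no filter on low counts, 642, 1118, 42, 3, 15 and 27 with the 2 groups alone and 148, 247, 0, 0, 6 and 8 at an adjusted p under 0.01. Against a 1.5-fold change they were 0, 0, 0, 0, 1 and 0 (309, 105, 128, 86, 129 and 75 at an unadjusted p under 0.05, edgeR). With all 15 libraries and no batch term they were 91, 702, 9, 3, 2 and 146, and shared genes went from 265, 2 and 2 to 75, 4 and 5 (Mel321-31 with Mel322-34, Mel321-31 with Mel321-35 and Mel322-34 with Mel321-35), or medians of 12, 0 and 0 with the controls split, where fewer controls stood behind each call. With the replicate number as a block they were 636, 1209, 5, 6, 23 and 16, although the numbers did not pair the samples by the rule that every same-number pair correlates above 0.1 (correlation of same-number pairs -0.151 to 0.261, median 0.0453, 18 pairs). As a hint from the data, 7 of 14 libraries correlated best with 1 of their own number. Replicate 3 of Mel322-34 correlated with that of Mel321-35 at 0.261 and with that of MGO.53 at 0.213, and replicate 3 of Mel321-35 with that of MGO.53 at 0.171. Pairs of other numbers ran from -0.358 to 0.272 (median 0.00151). How many of the 14 would do so by chance was not worked out, and the batch 1 libraries of Mel321-35 mirror each other by construction. With the covariate they were 5, 371, 52, 2, 0 and 78 and with the length trend removed 429, 411, 25, 2, 16 and 23. The 3 other scalings and the stricter filter kept all 6 counts within 1.5 times. So did all 15 libraries with a batch term, but that term absorbs the 1 batch 2 library, so little change was possible. The fit without the 95 transcripts did so too, but it leaves the counts of the other genes as they were. These last 2 fits therefore say little about stability.

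With the summed amount of the 95 transcripts as a covariate, 5 genes passed for Mel321-31, chosen after their values were seen. Hspe1 (0.33), Aifm1 (0.36), Ptms (0.34) and Hmgn5 (0.65) were higher, with adjusted p from 0.0437 to 0.0497 (edgeR). Adarb2 was lower at -12.5 ± 1.66 (SE), a size far beyond the others that may not be a reliable estimate. The interferon list, which shares 9 genes with that amount, went from a median of -0.72 to -0.031 with a median SE of 0.164 before and 0.170 after, and Isg15 from -1.07 ± 0.16 to -0.14 ± 0.12, so these calls ended because the change shrank. That shrinkage was fixed in part beforehand, since the amount holds members of the list and separates every Mel321-31 library from every MGO.53 library, so it says nothing about the source. Over all genes the median SE went from 0.0732 to 0.110, and the ribosomal protein list went from -0.080 to -0.052, so for other genes the calls ended with a wider error as well.

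Lists that passed numbered 0, 1, 0, 3, 0 and 1 with an estimated correlation, 1, 9, 1, 3, 1 and 1 with fry, which does not compare a list with other genes, and 5, 12, 9, 11, 7 and 6 with the covariate. For Mel322-34 against Mel321-35 they were 9 with all 15 libraries and no batch term and 3 with the length trend removed. Among single genes 5 turned direction, all with the covariate and for Mel321-31 against MGO.53: Apol9a 0.0075, Fosl1 0.33, Tap1 0.024, H2-D1 0.020, Egr1 0.16 (log2), none past the threshold there. A fit without MGO.53 replicates 2 and 4 together was also run after the data were seen and set aside, because those controls are picked by an amount that tracks the result. It gave no calls for Mel321-31 and Mel321-35 and fewer for Mel322-34 (edgeR), and is not used here. Depth ranged from 19.4 to 38.0 M counts, which limits calls of genes with few counts.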

Other observations

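Chosen only after the result was seen were the genes named here by count, while the tests on other splits of the libraries were set before. Lists and antibodies left out of the report's account of passing lists are given first, with camera adjusted p in the order Mel321-31, Mel322-34 and Mel321-35. With Mel322-34, 5 of 23 apoptosis genes rose, the inhibitors Cflar (0.18), Bcl2 (0.21), Xiap (0.19) and Birc2 (0.28) and the caspase activator Apaf1 (0.16), and the effector Bak1 fell (-0.20), with 5 higher and 3 lower adjusted over the list alone (list p 0.739, 0.397 and 0.190). The p53 targets Trp53inp1 (0.39), Ccng1 (0.15), Rrm2b (0.25), Zmat3 (0.14) and Mdm2 (0.14) rose and Gdf15 fell (-0.72), with 6 higher and 1 lower adjusted over the list alone and a list p of 0.0530, while with Mel321-31 Gdf15 (-1.40) and Fas (-1.86) fell (list p 0.603). Gdf15 is a batch-1-only transcript. Among 23 invasive genes, those that rose with Mel322-34 included fibronectin Fn1 (0.24) and Ccn2 (0.25), and Axl fell with Mel321-31 (-0.55) (list p 0.699, 0.159 and 0.696). With fry the invasive list passed for Mel322-34 (adjusted p = 0.0374, median log2 fold change 0.031). The pigment genes Pmel (-0.11), Trpm1 (-0.12) and Sox10 (-0.10) fell with Mel322-34, with 1 higher and 6 lower adjusted over the list alone (list p 0.867 for Mel321-31 and 0.214 for Mel322-34).

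Toll-like and HSP70 receptor genes had 0 of 16 called with any of the 3 antibodies (edgeR, 3, 4 and 0 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom, list p 0.699, 0.856 and 0.380), and 1, 0 and 0 were lower adjusted over the list alone. The unfolded protein response had 0 of 21 called (edgeR, 5, 7 and 2 at an unadjusted p under 0.05, 1, 5 and 0 by DESeq2, 1, 1 and 0 by limma-voom, list p 0.315, 0.287 and 0.729), with 0, 2 and 0 higher and 0, 3 and 0 lower adjusted over the list alone. The list p was 0.764, 0.946 and 0.696 for glycolysis, 0.699, 0.364 and 0.0940 for cholesterol synthesis, 0.764, 0.282 and 0.875 for lysosome and autophagy and 0.602, 0.748 and 0.641 for replication-dependent histones. It was 0.761 and 0.546 for fatty acid synthesis with Mel321-31 and Mel322-34, 0.0644 for G2 and mitosis, 0.355 for DNA replication and 0.579 for ribosome biogenesis with Mel321-31, and 0.593, 0.380 and 0.778 for integrated stress response, immediate early genes and NRF2 targets with Mel321-35. Among markers of other cells, Fbln2 (-1.15) and Cd74 (-1.22) fell with Mel321-31 and Fbln1 fell with Mel322-34 (-0.17) (list p 0.0644, 0.287 and 0.161 for fibroblasts and 0.224, 0.856 and 0.729 for macrophages), each list holding 1 batch-1-only transcript. The median or mean had another sign than the test, in lists that did not pass, for Mel321-31 (apoptosis, fatty acid synthesis), Mel322-34 (p53 targets, melanocyte differentiation, invasive and mesenchymal genes, glycolysis, fatty acid synthesis) and Mel321-35 (integrated stress response, glycolysis, replication-dependent histones). The lymphocyte, keratinocyte and endothelial lists were not tested, as too few members were expressed, with maxima over the libraries of 2.32 CPM for Lck and 0.397 for Cd79a, 4.77 for Sfn and 2.73 for Dsp, and 419 for Eng and 9.67 for Egfl7.

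The 8 libraries of each pair of groups with n = 4 were split in all 35 ways into 4 and 4. For genes, only the real split gave as many as 517 for Mel321-31 against MGO.53, and the highest other gave 180. A share of 1 in 35 is the smallest that these splits can give, so chance is not excluded by it alone. The real split also stood alone for Mel322-34 against MGO.53 (1 split, 1005 genes, highest other 105). For Mel321-31 against Mel322-34 the real split stood alone with all 8 libraries (1 split, 3 genes, highest other 1), while the 3 genes became 0 without Mel321-31 replicate 2, 3 or 4 or Mel322-34 replicate 1 or 4 (edgeR, 1001 to 1111 at an unadjusted p under 0.05). For lists by camera, the real split stood alone for Mel321-31 against MGO.53 (1 split, 10 lists, highest other 8), but all 10 calls were lost with adjusted p from 0.174 to 0.771 with an estimated correlation, and 8 passed without Mel321-31 replicate 3 or 4 or MGO.53 replicate 1 or 3. The real split did not stand alone in lists for Mel322-34 against MGO.53, where 3 splits gave at least the 13 lists of the real one and the highest other gave 14, nor for Mel321-31 against Mel322-34, with 2 splits, 13 lists and a highest other of 13. Comparisons with Mel321-35 had n = 2 on 1 side and were not split.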
